A study of Mus musculus with 46 samples.

How the data were processed

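Libraries came from crosslinked XEN cells by sisHi-C with MboI, per the labels' protocols. Per the submitters' processing notes, the pairs were made with HiC-Pro 2.11.1 on mm9. The deposited tables list valid read pairs, and the authors split them between Xa and Xi and pooled the samples of a group, per the file names. How the split between homologues was made, which parental strain each homologue stood for, and whether duplicates were removed by a stated rule are not given in the sources used here. Each line of the deposited tables holds the position and strand of both ends and a mapping quality score for each end. All pairs had both ends on the X. No normalised values were used from the authors.

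The series' labels give 46 samples in 13 groups. There were 6 files in use: an Xa and an Xi file each for Ctcf DMSO (2 samples), Ctcf dTAG (2 samples) and Rad21 dTAG (10 samples of 2 clones). Pairs of the other 10 groups, Rad21 DMSO among them, were not used here. Every value refers to a pooled file. No test across replicates was made and no p-value is given, and reads amplified by PCR are not independent molecules, so that the intervals cover counting error only. Read names showed 2 sequencing lanes in the Ctcf files and 5 in the Rad21 files. Lanes were analysed alone as a technical split and were not treated as replicates. Pairs with the same positions and strands at both ends as another pair numbered 0 in both Ctcf DMSO files, 2 and 1 in the Ctcf dTAG files, and 604 and 492 in the Rad21 dTAG files.

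Pairs at 20 kb or more were binned and balanced by iterative correction with 50 rounds, leaving out bins with under 25% of the median count. Observed over expected divided each bin pair by the mean at its distance on the same X. Shares of pairs by distance have Clopper-Pearson 95% intervals. The decay slope is the log-log derivative of contact density over 10 bins per decade, smoothed over 3 bins, and its peak was searched from 40 kb to 1 Mb.

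The split score used 500 kb bins, 20 Mb flanks and bin pairs 2 to 20 Mb apart. It is log2 of the mean observed over expected within both flanks over that across the edge. Its positions were the best edges of Ctcf DMSO Xi from 99.5 to 101.5 Mb (Xist) and from 72 to 74 Mb (Dxz4), then fixed for all files. The edge chosen for Dxz4, 72 Mb, lay at the border of its range.

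Insulation was computed on 40 kb bins with a 400 kb diamond, as log2 over the mean of the X. Boundaries were minima with a depth of at least 0.2, where depth is the mean score 200 to 400 kb away minus the score at the boundary. They were called on a random part of the Ctcf DMSO Xa pairs, which gave 131, and measured in the remaining pairs and in the other files, so that calling and measuring used different pairs. The boundary of each named locus was the deepest edge on Ctcf DMSO Xi within 100.4 to 101 Mb (Xist), 72.5 to 73.5 Mb (Dxz4) or 47.5 to 48.5 Mb (Firre), a choice made after the data were seen, which favours the depth of that file. The SD of the insulation score used files thinned to 1393898 pairs.

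Compartment strength is log2 of mean observed over expected within the highest and the lowest of 5 equal parts of the bins over that between these parts, at 2 Mb or more, with the first eigenvector of Ctcf DMSO Xa for all files. Contacts between Firre, Dxz4 and Xist were raw pairs between 500 kb windows centred at 48, 73 and 100.75 Mb, with exact Poisson intervals, against all window pairs at the same distance. For the other measures, 100 Poisson bootstrap draws over pairs gave intervals of the value plus or minus 1.96 SD of the draws, or percentiles of the draws for positions. The additional tests of Firre used 30 draws. The break in Xi contacts was located, after the data were seen, as the edge covered on both sides that the fewest Ctcf DMSO Xi pairs crossed relative to the Xa. The SD form replaced percentile intervals after a trial of 3 draws, since resampling shifted the draws of depths and SDs upward. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.

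The functions were tested on simulated sets of 1400000 pairs. A planted split of 0.5 was measured as 0.43, and a set without a split gave 0.00. These sets held no compartments, so they do not show how the score responds to compartments. Of 108 planted boundaries of 0.5, 97.2% were called, with 8 calls elsewhere. A set without boundaries gave 38 calls, of which 37 lay away from the planted positions.

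The named positions followed a rule fixed before the data were examined: Xist, Dxz4 and Firre, the 10 deepest boundaries, the 10 largest losses and 5 largest gains in Ctcf dTAG Xa among boundaries with at least median coverage, and the 10 highest and 5 lowest 1 Mb windows of the Xi to Xa ratio of short-range contacts. The gene table given with the data describes GRCm38.p6 and the pairs are on mm9, so no gene was attached to other positions, and the planned contacts of escape genes and silenced genes were not run. Values for autosomes were not analysed here. Alternatives were set beforehand for bin size, balancing, flanks, distances, thinning, mapping quality and lanes, and others were added after seeing the data.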

Results

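Chromosome conformation was measured by sisHi-C, a small-input form of in situ Hi-C with MboI digestion, in XEN cells, extraembryonic endoderm stem cells of mouse. The line was 129S1/SvImj X JF1/Ms, so that read pairs of the X could be split between the active homologue (Xa) and the inactive homologue (Xi). The series held 46 samples in 13 groups of wild-type and mutant lines. X pairs of 3 groups were analysed here. These were cells with a degradable CTCF given DMSO or the degrader dTAG for 48 h (2 samples each), and cells with a degradable RAD21, a cohesin subunit, given dTAG for 24 h (10 samples, 7 of clone 1 and 3 of clone 2). CTCF is the DNA-binding protein at many domain boundaries, and cohesin is the ring complex that extrudes chromatin loops. Each group and homologue was a single pooled file, so there was no replicate error, the clones could not be compared, and every interval below is a 95% interval for counting error only.

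The Ctcf DMSO files held 3290785 Xa and 1695546 Xi pairs, the Ctcf dTAG files 4005319 and 2103881, and the Rad21 dTAG files 3873235 and 3155860. Pairs at 20 kb or more, on which all maps were built, numbered from 1393898 in Ctcf DMSO Xi to 3295080 in Rad21 dTAG Xa. The median 40 kb bin held 717 ends in Ctcf DMSO Xi and 1234 in Ctcf DMSO Xa. Pairs with a mapping quality under 30 at either end made up 22.4% of Ctcf DMSO Xa and 32.3% of Ctcf DMSO Xi.

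The first comparison asked how the Xi differed from the Xa in the control cells. The Xi had a smaller share of contacts in the size range of domains and loops and a larger share at long range. Of pairs at 20 kb or more, 40.6% lay 100 kb to 1 Mb apart on the Xa (95% Clopper-Pearson interval 40.6 to 40.7) and 30.8% on the Xi (30.7 to 30.9). Pairs beyond 10 Mb made up 18.8% on the Xa (18.8 to 18.8) and 27.4% on the Xi (27.3 to 27.5), and those beyond 50 Mb 2.46% and 8.83%. A uniform background of up to 8.96% of pairs was possible in Ctcf DMSO Xi. It was not removed from these shares and was not computed for the Xa. In all 144 windows of 1 Mb that could be measured, the share of ends in short-range contacts of 20 kb to 1 Mb was lower on the Xi than on the Xa, with a median ratio of 0.766. The contact decay slope still had a local peak on both homologues, at 70.8 kb with a slope of -0.73 on the Xa (-0.73 to -0.72) and at 112 kb with a slope of -0.72 on the Xi (-0.74 to -0.71).

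**Figure D1:**
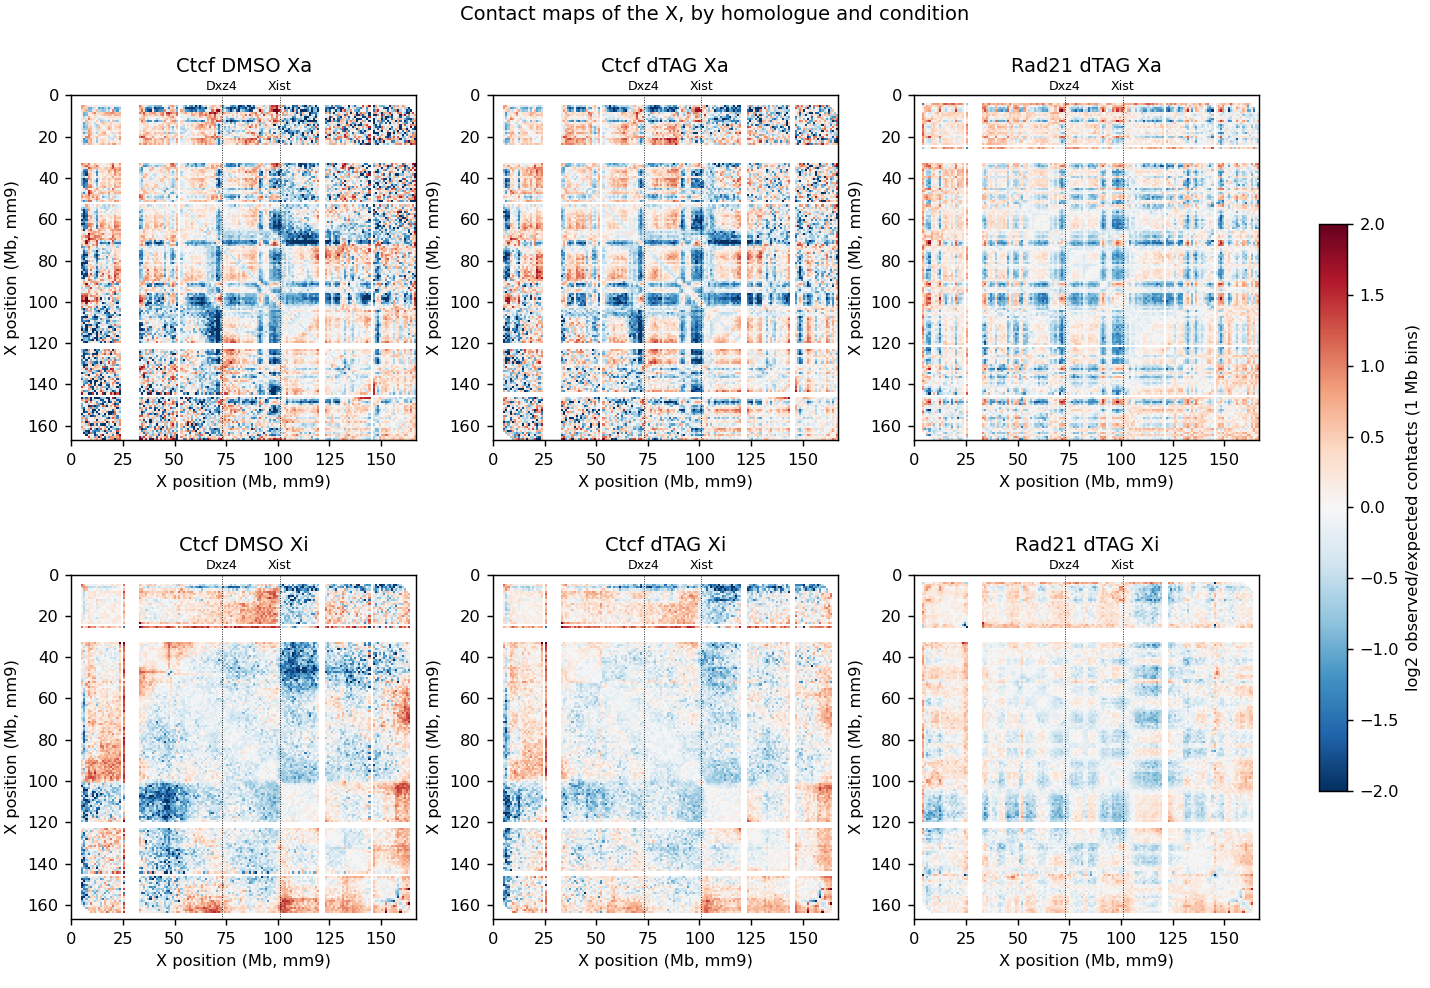
Contact maps of the X for the 6 files, with both axes in Mb of mm9 and colour giving log2 of observed over distance-expected contacts in 1 Mb bins (blank bins were masked). Contacts across Xist were depleted on both homologues of Ctcf DMSO, with split scores of 0.46 on the Xi and 0.55 on the Xa.

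Domains and the compartment pattern of the Xa were both weaker on the Xi. At 128 boundaries that were called on a random part of the Ctcf DMSO Xa pairs and could be measured on both homologues, the Xi was lower at 94 and higher at 3 by more than counting error. Mean depth over all measurable boundaries was 0.56 on the Xa (0.55 to 0.57), taken from the pairs not used for calling, and 0.20 on the Xi (0.18 to 0.21). These positions were chosen on the Xa. Boundaries called anew in each file, on the pairs that also measured them, had a mean depth of 0.60 on the Xa (131 boundaries) and 0.44 on the Xi (74). For the Xa this used only the pairs left out of the first calling. Depth at the positions chosen on the Xa reached 0.2 at 117 of 128 on the Xa and at 50 on the Xi. After thinning to 1393898 pairs, the SD of the insulation score along the X was 0.33 on the Xa (0.32 to 0.33) and 0.24 on the Xi (0.23 to 0.25). Compartment strength on the eigenvector of the Xa was 1.55 on the Xa (1.51 to 1.58) and 0.37 on the Xi (0.35 to 0.40). That eigenvector came from the same Xa pairs, which favours the Xa. The first eigenvector of the Xi had an absolute correlation of 0.0213 with it, so compartments of the Xi's own were not measured by this value.

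The Firre locus stood apart from this trend. For Firre, Dxz4 and Xist, the deepest edge of Ctcf DMSO Xi near each locus was measured, a choice made after the other boundaries had been fixed and one that favours the depth of that file. Firre, a locus of a noncoding RNA with many CTCF sites, had this edge at 47.96 Mb with a depth of 1.57 on the Xi (1.35 to 1.78) and 1.04 on the Xa (0.87 to 1.2). The boundary called at 48 Mb without use of the Xi had 1.51 on the Xi and 0.93 on the Xa. At 100.6 Mb beside Xist, the gene of the RNA that coats the Xi, depth was 0.56 on the Xi (0.46 to 0.66) and 0.54 on the Xa (0.44 to 0.63), whereas the boundary called at 100.64 Mb without use of the Xi was lower on the Xi, with 0.55 (0.44 to 0.66) against 0.80 (0.69 to 0.91). At 72.92 Mb near Dxz4, a macrosatellite with CTCF sites, depth was lower on the Xi, as at most boundaries, with 0.39 (0.23 to 0.56) against 1.15 on the Xa (1.02 to 1.28).

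The split of the chromosome into 2 large domains was scored as log2 of contacts within over across each 500 kb edge, 2 to 20 Mb apart. Whether compartments contribute to this score was not tested. In control cells the highest of 255 edges was at 101.0 Mb, next to Xist, on both homologues, with a score of 0.46 on the Xi (0.42 to 0.49) and 0.55 on the Xa (0.53 to 0.57). The edge chosen at Dxz4, 72 Mb, scored 0.059 on the Xi (0.031 to 0.086), with 76 edges higher, and 0.43 on the Xa (0.41 to 0.46), with 15 higher. At Dxz4 the Xi scored 0.11 and the Xa 0.17 with bins 1 to 40 Mb apart. At Xist the order turned at a wider range, chosen after seeing the data: with bins 10 to 60 Mb apart and flanks of 60 Mb, the Xi scored 0.38 at Xist (0.36 to 0.39) and the Xa 0.25 (0.24 to 0.27), while at Dxz4 they scored 0.16 and 0.31. At that range the highest edge was at 100.5 Mb on the Xi and at 72.5 Mb on the Xa. A flank of 10 Mb also put the Xi above the Xa at Xist, by 0.15.

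**Figure D2:**
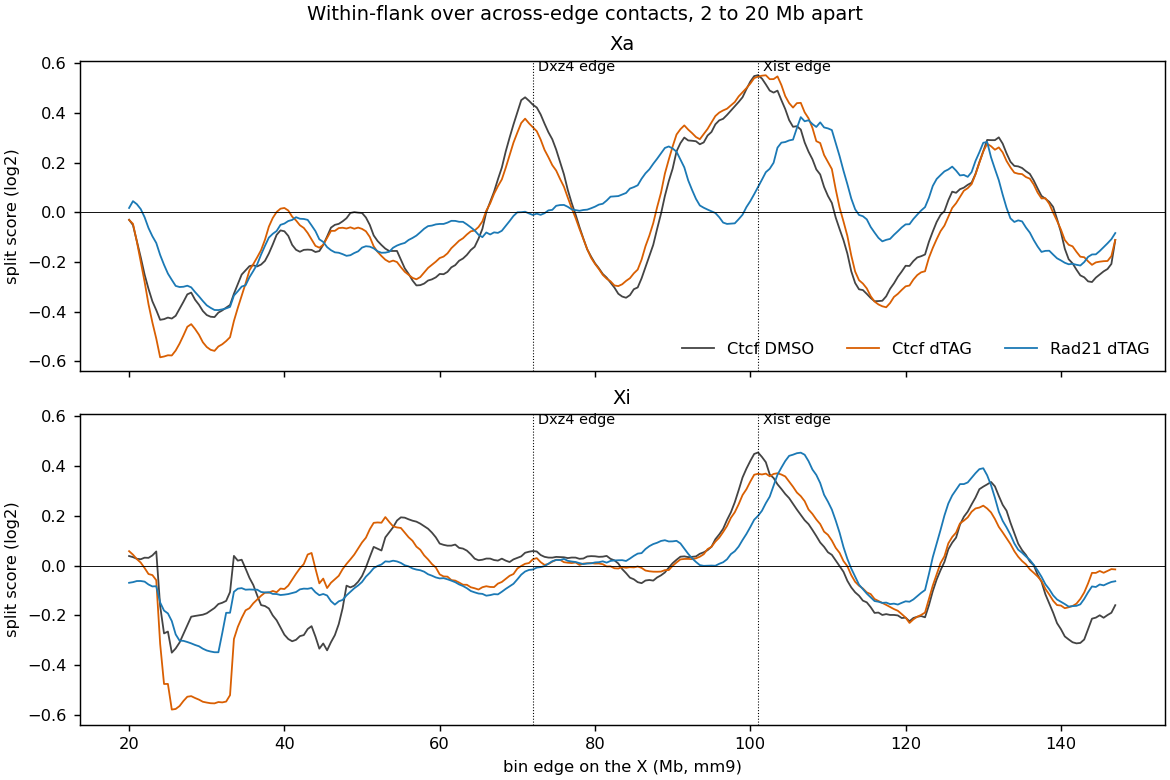
Split score (log2 of contacts within over across an edge, 2 to 20 Mb apart) at each 500 kb edge of the X in Mb of mm9, for Xa (top) and Xi (bottom), with a line per condition. On both homologues the Ctcf DMSO line peaked at 101.0 Mb, at Xist, and the Rad21 dTAG line at 106.5 Mb.

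No contact enrichment between Firre, Dxz4 and Xist was detectable on the Xi. Between 500 kb windows at Firre and Dxz4, Ctcf DMSO Xi had 10 pairs where 14.2 were the mean at that distance, a ratio of 0.706 (exact Poisson interval 0.338 to 1.30), at percentile 30.5 of 453 window pairs. Dxz4 with Xist gave 0.861 (0.430 to 1.54) and Firre with Xist 0.917 (0.419 to 1.74). On the Xa, Dxz4 with Xist gave 1.73 (1.26 to 2.32), from 45 pairs and at percentile 91.9 of 458 window pairs, Firre with Dxz4 1.39 (0.979 to 1.92) and Firre with Xist 0.939 (0.377 to 1.93). Counts this low leave an enrichment of up to 1.30 between Firre and Dxz4 open on the Xi.

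The second comparison asked how the homologues differed between dTAG and DMSO in the cells with degradable CTCF. On the Xa, the boundaries called with DMSO were shallower with dTAG along most of the chromosome. Mean depth was 0.56 with DMSO and 0.25 with dTAG (0.24 to 0.26), a difference of -0.31 (-0.32 to -0.30), so that 44.9% of the depth at these positions remained. Of 131 boundaries, 87 were lower and 7 higher by more than counting error. Depth of at least 0.2 was found at 120 with DMSO and at 69 with dTAG. These positions were chosen with DMSO, so a boundary that moved counts as lost depth. When called anew in each file, boundaries had a mean depth of 0.60 with DMSO (131 boundaries) and 0.45 with dTAG (116).

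The deepest boundary in the calling pairs, at 70.16 Mb, went from 1.78 (1.54 to 2.01) to 0.51 (0.41 to 0.60), which was also the largest loss of the chromosome among those with at least median coverage. The 10 deepest boundaries were all lower with dTAG, with differences from -1.27 at 70.16 Mb to -0.45 at 103.4 Mb. Among the 10 largest losses, those at 13.28, 45.32, 56.4 and 94.68 Mb ended below 0 by more than counting error, from 0.73, 0.78, 0.46 and 0.55, and that at 140.12 Mb ended at -0.023 with an interval that held 0, from 0.77. The 5 largest gains were smaller, from 0.14 at 114.64 Mb to 0.59 at 160.36 Mb, where depth went from 0.27 to 0.86. Firre went from 1.04 to 0.54 (0.46 to 0.61), Dxz4 from 1.15 to 0.77 (0.68 to 0.86) and the edge beside Xist from 0.54 to 0.36 (0.32 to 0.41) at 100.6 Mb and from 0.80 to 0.43 (0.38 to 0.48) at 100.64 Mb.

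**Figure D3:**
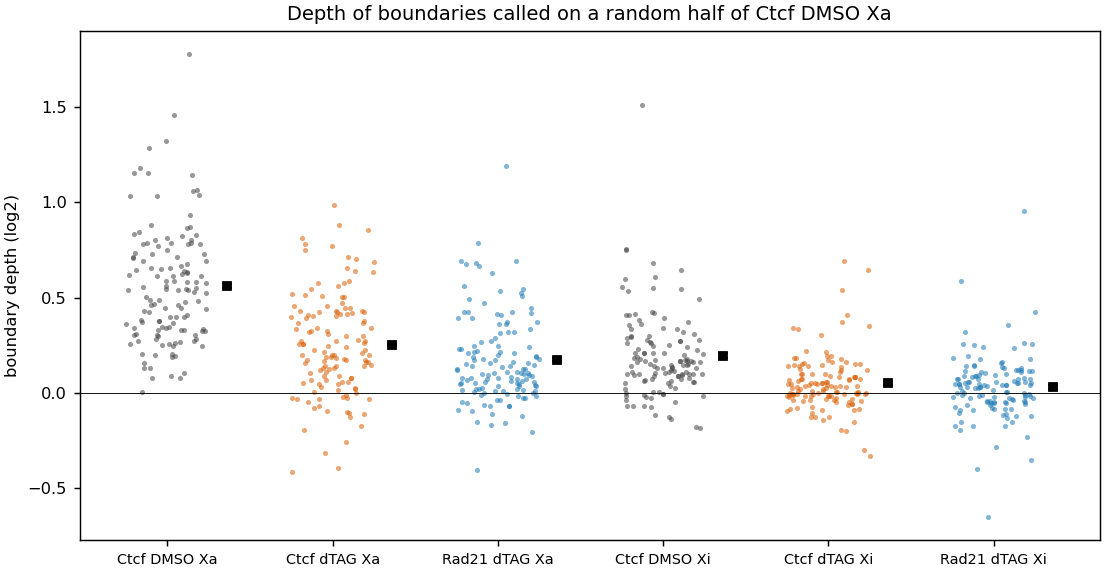
Depth (log2) of each boundary called on a random part of the Ctcf DMSO Xa pairs, as points, in the 6 files, with the mean and its 95% counting interval as a black square beside them. Mean depth was 0.56 in Ctcf DMSO Xa, 0.25 in Ctcf dTAG Xa and 0.054 in Ctcf dTAG Xi.

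On the Xa, the shares of pairs by distance and the slope at its peak moved little. The share of pairs from 100 kb to 1 Mb was 42.8% with dTAG (42.8 to 42.9) against 40.6% with DMSO, and that beyond 10 Mb was 17.4% (17.3 to 17.4) against 18.8%. The slope at its peak was -0.72 (-0.73 to -0.71), with a difference of 0.0065 whose interval held 0 (-0.0056 to 0.019). Compartment strength was 1.48 (1.46 to 1.51) against 1.55, a difference of -0.062 (-0.10 to -0.019) that turned to 0.11 over pairs 2 to 40 Mb apart and to 0.037 on each file's own eigenvector. The split score at Xist was 0.55 in both files, but this depended on range. At 10 to 60 Mb it was 0.18 with dTAG against 0.25, a difference of -0.070 (-0.087 to -0.053), and the difference was -0.078 at 1 to 40 Mb and 0.056 with flanks of 10 Mb. The score at Dxz4 was 0.34 (0.32 to 0.36) against 0.43.

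On the Xi, depth at the boundaries called on Ctcf DMSO Xa was also lower with dTAG than with DMSO. Mean depth was 0.20 with DMSO and 0.054 with dTAG (0.044 to 0.064), a difference of -0.14 (-0.16 to -0.13). Of 128 boundaries, 51 were lower and 1 was higher by more than counting error. When called anew in each Xi file, boundaries were fewer with dTAG. Their mean depth was 0.44 with DMSO (74 boundaries) and 0.53 with dTAG (32). Only boundaries with a depth of at least 0.2 were called, so this mean can rise when shallow boundaries drop out. The Firre boundary went from 1.57 to 0.086 (-0.030 to 0.20), a difference of -1.48 (-1.73 to -1.23). By eye, the stripes that ran from Firre in the control map were no longer visible, but stripes were not measured. The boundary near Dxz4 went from 0.39 to -0.0025 (-0.13 to 0.13). The edge beside Xist at 100.6 Mb was 0.49 with dTAG (0.40 to 0.57), and its difference of -0.074 lay within counting error (-0.20 to 0.057). The boundary called at 100.64 Mb went from 0.55 (0.44 to 0.66) to 0.41 (0.33 to 0.49).

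**Figure D4:**
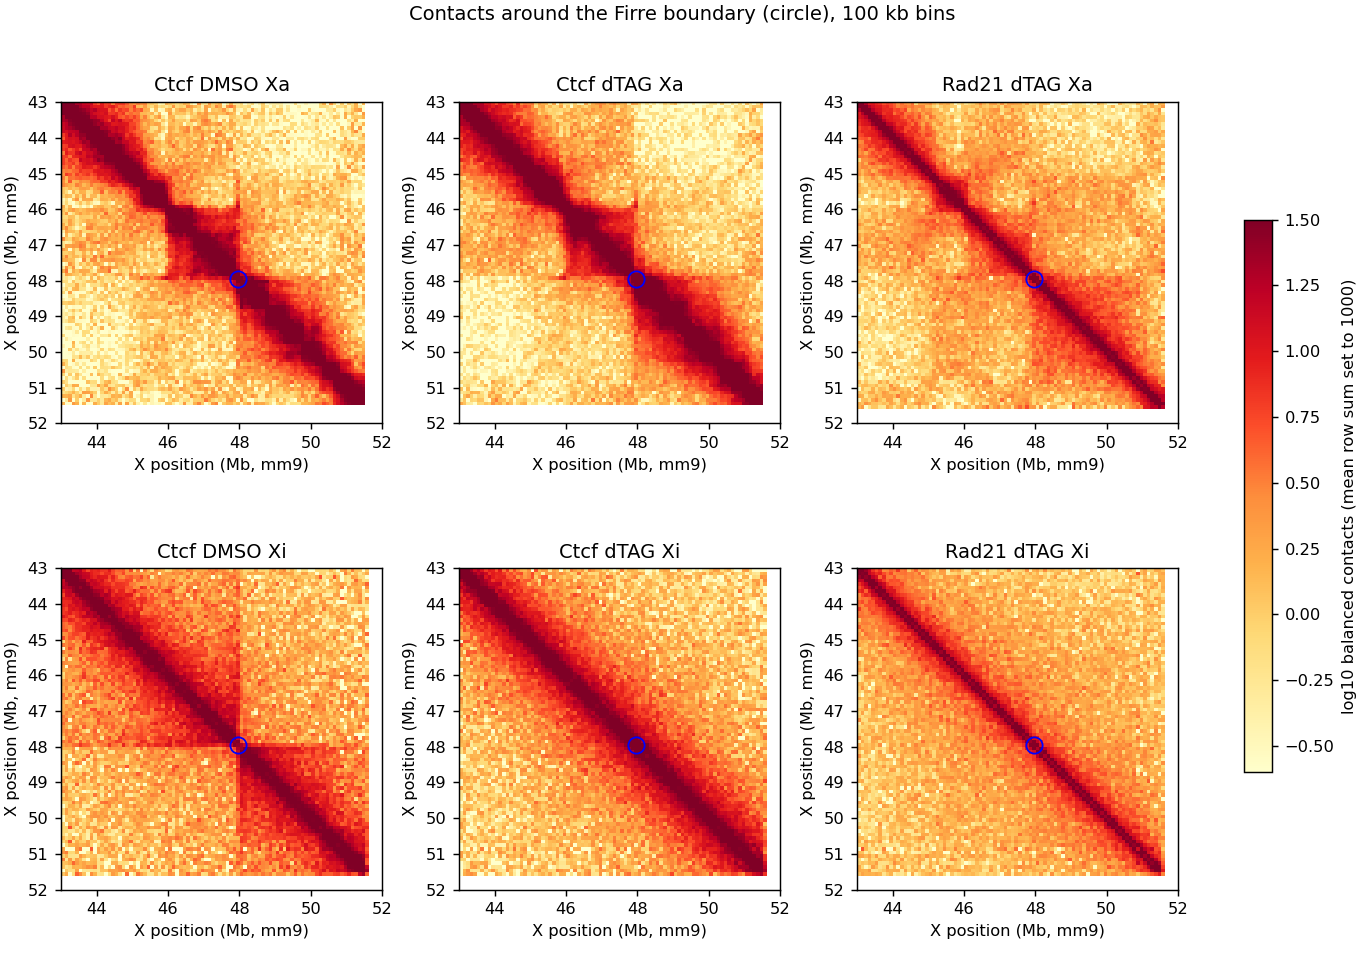
Balanced contacts (log10, mean row sum set to 1000) in 100 kb bins from 43 to 52 Mb of the X (mm9, both axes) in the 6 files, with the Firre boundary at 47.96 Mb circled and masked bins blank. Boundary depth there was 1.57 in Ctcf DMSO Xi, 0.086 in Ctcf dTAG Xi and 0.056 in Rad21 dTAG Xi.

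The split of the Xi at Xist was kept at reduced height. The score at 101.0 Mb was 0.46 with DMSO and 0.37 with dTAG (0.34 to 0.40), a difference of -0.086 (-0.13 to -0.046), and 2 edges scored higher with dTAG, with the maximum of 0.37 at 103.5 Mb. The drop depended on range: it was -0.13 with flanks of 10 Mb, -0.023 at 10 to 60 Mb, and 0.00035 at 1 to 40 Mb with flanks of 40 Mb. The shares of pairs from 100 kb to 1 Mb were 30.8% and 32.0% (31.9 to 32.1), and those beyond 10 Mb 27.4% and 28.0% (28.0 to 28.1). Compartment strength was 0.33 with dTAG (0.31 to 0.35) against 0.37. The SD of the insulation score was 0.22 (0.21 to 0.23) against 0.24, which turned upward with raw counts. Between Firre and Dxz4 the contact ratio was 0.781 with dTAG (0.416 to 1.33), from 13 pairs.

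The third set of values asked how both homologues looked in cells with degradable RAD21 given dTAG. The Rad21 dTAG files pooled 2 clones of other cells, with 24 h of treatment, and DMSO pairs of those clones were not used here, so these values are set beside Ctcf DMSO without a treatment effect being drawn from them. Contacts in the domain range made up a smaller share in the Rad21 files. The share from 100 kb to 1 Mb was 17.4% on the Xa (17.3 to 17.4) and 14.8% on the Xi (14.8 to 14.9), against 40.6% and 30.8% in Ctcf DMSO. Pairs beyond 10 Mb made up 47.4% on the Xa (47.3 to 47.4) and 52.3% on the Xi (52.2 to 52.3). The largest uniform background that the maps allowed was 41.4% of pairs on Rad21 dTAG Xi and 8.96% on Ctcf DMSO Xi, and it was not removed from these shares. The slope peak at 70.8 to 112 kb of the Ctcf files was missing on the Xa. The Xi had only a shallow local maximum of -1.01 at 70.8 kb, between -1.03 at 56.2 kb and -1.04 at 112 kb. In the searched range the slope was highest at 891 kb, the last bin searched, at -0.88 on the Xa (-0.89 to -0.87) and -0.81 on the Xi (-0.83 to -0.80).

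**Figure D5:**
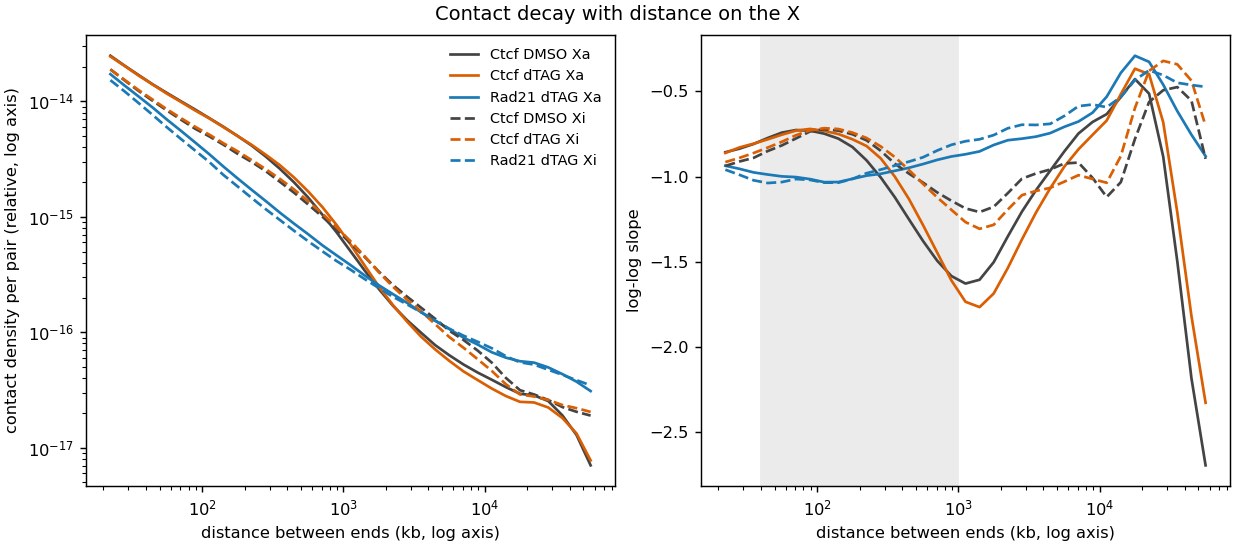
Contact density per pair (left, both axes log) and its log-log slope (right) against the distance between ends in kb, with solid lines for Xa and dashed lines for Xi, and the searched range of 40 kb to 1 Mb in grey. The Ctcf files had a slope of about -0.72 near 100 kb. Rad21 dTAG had no peak there on the Xa and only a shallow local maximum, of -1.01 at 70.8 kb, on the Xi.

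Mean boundary depth in Rad21 dTAG was 0.17 on the Xa (0.17 to 0.18) and 0.032 on the Xi (0.021 to 0.043). The Xi value was 0.020 with a mapping quality of at least 30, which 43.3% of its pairs did not reach, and 0.068 with raw counts. These positions were chosen on Ctcf DMSO Xa. When called anew in the Rad21 dTAG files, boundaries had a mean depth of 0.45 on the Xa (69 boundaries) and 0.38 on the Xi (39). The SD of the insulation score in thinned files was 0.24 on the Xa (0.24 to 0.25) against 0.33 in Ctcf DMSO. On the Xi it was 0.24 in both, with a difference of -0.0029 whose interval held 0 (-0.019 to 0.013). Over 5 alternatives that Xi difference ran from -0.12 to 0.078. Against Ctcf DMSO, 107 of 131 boundaries were lower and 1 higher by more than counting error on the Xa, and 51 of 128 were lower and 3 higher on the Xi. Depth of at least 0.2 was found at 45 positions on the Xa and at 11 on the Xi. Firre had a depth of 0.37 on the Xa (0.24 to 0.49) and 0.056 on the Xi (-0.082 to 0.19), and the edge beside Xist 0.26 (0.15 to 0.36) and 0.33 (0.18 to 0.48) at 100.6 Mb, and 0.23 (0.12 to 0.33) and 0.15 (0.016 to 0.28) at 100.64 Mb. On the Rad21 dTAG Xi the contact ratio was 0.857 between Firre and Dxz4 (0.612 to 1.17), 1.13 between Firre and Xist (0.791 to 1.56) and 0.632 between Dxz4 and Xist (0.420 to 0.913), the last at percentile 11.3 of 450 window pairs. The boundary at 7.84 Mb had 1.19 on the Xa (1.06 to 1.32) against 1.14 in Ctcf DMSO (1.01 to 1.28). Coverage differed at that place too: the 1 Mb window starting at 7 Mb had a log2 ratio of -1.18 between the Rad21 dTAG and Ctcf DMSO Xa files, the lowest of 144 windows.

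The split at Xist was lower in Rad21 dTAG on both homologues. The score at 101.0 Mb was 0.20 on the Xi (0.18 to 0.22) and 0.10 on the Xa (0.085 to 0.12), with 34 and 55 of 255 edges higher. The difference from Ctcf DMSO was -0.25 on the Xi and -0.45 on the Xa, and -0.40 and -0.23 with flanks of 10 Mb. The Xi still had a maximum of 0.45 (0.44 to 0.47), but at 106.5 Mb, where the Xa also had its maximum, of 0.38 (0.37 to 0.40). At 10 to 60 Mb the Xi scored 0.13 at Xist (0.12 to 0.14) against 0.38 in Ctcf DMSO. Compartment strength was 0.58 on the Xi (0.56 to 0.59) against 0.37 in Ctcf DMSO, and 1.40 on the Xa (1.39 to 1.41) against 1.55. Across 5 sequencing lanes it ranged from 0.55 to 0.70 on the Xi and from 1.35 to 1.65 on the Xa, so the lower value on the Xa did not hold in each lane. The first eigenvector of Rad21 dTAG Xi had an absolute correlation of 0.724 across 290 bins with that of Ctcf DMSO Xa, against 0.0213 for Ctcf DMSO Xi (the bins of 1 chromosome are not independent replicates). Only first eigenvectors were compared, and Ctcf DMSO Xi still had a strength of 0.37 on that of the Xa. Xi pairs across the break in Xi contacts were 2.81% of the Xa pairs there in Rad21 dTAG and 0.547% in Ctcf DMSO. Whether Xa pairs in the Xi file raised the correlation was not tested.

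Along the chromosome, the gap between Xi and Xa in the share of short-range contacts was uneven. The lowest ratios of Xi to Xa in Ctcf DMSO were in the windows starting at 71, 33, 159, 72 and 70 Mb, from 0.534 to 0.589, and 3 of these 5 formed the stretch from 70 to 73 Mb beside Dxz4. In the window at 71 Mb, 78.7% of Xa ends and 42.0% of Xi ends were in short-range contacts. The highest ratio was 0.941 at 84 Mb, where the shares were 47.0% of Xa ends and 44.2% of Xi ends. Between the windows at 71 and 84 Mb, the share differed far more on the Xa than on the Xi. These windows were picked for their extreme ratios, which favours such a gap, so it does not describe the chromosome as a whole. Of the 10 highest ratios, 7 lay between 78 and 88 Mb. In the same 2 windows the ratio was 0.557 and 0.938 in Ctcf dTAG, and 0.595 and 0.890 in Rad21 dTAG. The median over all windows was 0.760 in Ctcf dTAG and 0.868 in Rad21 dTAG.

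Coverage was even between the Ctcf files, with log2 ratios of dTAG to DMSO from -0.094 to 0.12 on the Xa and from -0.14 to 0.13 on the Xi over 144 windows. Between Xi and Xa in Ctcf DMSO it ran from -0.41 to 1.27, with the highest value in the window starting at 161 Mb. That window was also the highest in Ctcf dTAG, at 1.21, and in Rad21 dTAG, at 1.00. On the Xi, 4 pairs of ends 20 to 200 kb apart crossed 157.4 Mb in Ctcf DMSO against 731 on the Xa, and from 164.04 to 166.04 Mb the Xi had 219 ends against 111208 on the Xa. Both limit the Xi values given here for positions at or beyond 157.4 Mb.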

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

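The Firre tests, the mapping quality test at 157.4 Mb and the test of a uniform background were set before their results were seen, and the other tests in this part, those of reference order, of an extra copy, of Xa pairs and of the Rad21 cells, were chosen only after the result was seen.

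Contacts of the Xi broke at 157.4 Mb and rejoined elsewhere, a signal outside the planned comparisons and above its level on the Xa. Pairs joining 157 to 157.4 Mb with 159.76 to 160.16 Mb numbered 695 in Ctcf DMSO Xi, 884 in Ctcf dTAG Xi and 595 in Rad21 dTAG Xi, against 109, 117 and 158 on the Xa. The position of 159.76 Mb was chosen for the most Ctcf DMSO Xi contacts with 157 to 157.4 Mb, which favours the count of that file. On the Xa, contacts ran on across 157.4 Mb, with a lowest ratio of pairs across it to edges beside it of 0.729. The edge was chosen for few Xi pairs relative to the Xa, among edges well crossed on the Xa. A high Xa ratio was thus largely built in, and the test could not decide on a reference order wrong for both homologues. With a mapping quality of at least 30, the highest such ratio on the Xi was 0.0288. This filter only removes pairs, and no more than 8 crossed the break in any Xi file before it. A low ratio was thus built in, and this test could not decide on low mapping quality. A rearranged Xi with an extra copy of the distal part may account for the pattern: Xi over Xa coverage was at least 2.03 times as high from 159.86 to 163.24 Mb as from 157.5 to 159.26 Mb in each condition, and from 164.04 to 166.04 Mb it was 0.00381 to 0.00553 of that in the proximal part. This last range was placed where Xi coverage had ended, so a low value there was set by that choice. It remains a hypothesis found on these data, and other lines of the series were not used here to test it.

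The Firre boundary on the Xi was lower with Ctcf dTAG than with DMSO, with a difference of -1.48. The difference was -1.34 with a mapping quality of at least 30, -1.50 with the same number of pairs in both files, and -1.47 in the lane with the smaller drop, which argues against low mapping quality, depth or a single lane as the whole cause. Loss of CTCF at Firre is the biological explanation that the design gives. It stays a hypothesis, since CTCF at Firre was not measured here and each condition was 1 pooled file.

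The split at Xist was lower on Rad21 dTAG Xi than on Ctcf DMSO Xi. Removing the largest uniform background, 41.4% of pairs, gave a score of 0.38 (0.34 to 0.42), under the lower bound of 0.42 for Ctcf DMSO Xi without removal, which argues against background as the whole cause. The same removal took Ctcf DMSO Xi from 0.46 to 0.56 (0.52 to 0.60), so that a gap remained after it. Removing the Xa map scaled to 5.53% of the Xa pairs, the upper bound from pairs across the break, gave 0.21, which argues against Xa pairs in the Xi file; this form replaced a first one, a limit on that share, which had left the question undecided. The highest of 5 lanes scored 0.23, and the clones, the hours and the runs of the Rad21 file cannot be told apart from loss of RAD21.

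The share of pairs beyond 10 Mb differed between dTAG and DMSO by -1.43 percentage points on the Xa and by 0.637 on the Xi. The opposite sign came from summing classes that each moved the same way on both homologues: 10 to 50 Mb went from 16.3% to 14.5% on the Xa and from 18.6% to 17.8% on the Xi, and beyond 50 Mb from 2.46% to 2.90% and from 8.83% to 10.3%. The difference between them was not tested across replicates.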

How the results depend on the processing

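Alternatives without the distal end of the X, from shortly before the break in Xi contacts on, with bins 10 to 60 Mb apart, and with a mapping quality of at least 30 for measures other than the shares were chosen only after the data were seen. No paired analysis was possible because the replicates of each group were pooled in 1 file. Of 436 alternative values, 284 stayed within the counting interval, 142 moved beyond it and 10 reversed. For the Ctcf comparisons, 183 of 237 stayed. Mean boundary depth kept its direction in 10 of 10 alternatives in each Ctcf comparison. All of these used boundaries called on Ctcf DMSO Xa, so they did not vary that choice. With boundaries called anew in each file, mean depth on the Xi was 0.44 over 74 boundaries with DMSO and 0.53 over 32 with dTAG. On the Xa it was 0.60 with DMSO and 0.45 with dTAG. Only boundaries with a depth of at least 0.2 enter these means, which can rise when shallow boundaries drop out. They therefore do not give a direction of change in depth. The causes of the changes below were not tested.

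For Xi minus Xa in Ctcf DMSO, the share beyond 10 Mb differed by 8.24 points with a mapping quality of at least 30, 7.54 without the distal end and 8.46 with a minimum of 10 kb. The share from 100 kb to 1 Mb differed by -9.52, -9.13 and -8.61 in the same order, and by -11.6 with a minimum of 40 kb. The slope differed by 0.030 without smoothing. The score at Xist differed by -0.048 with raw counts, 0.15 with a flank of 10 Mb, -0.0020 at 1 to 40 Mb and 0.13 at 10 to 60 Mb, and that at Dxz4 by -0.25, -0.064 and -0.15 with the last 3 settings. Boundary depth differed by -0.44 with a minimum depth of 0.4, and insulation SD by -0.10 without the distal end and -0.17 with raw counts. Compartment strength differed by -1.97 on each file's own eigenvector, -1.09 with 1 Mb bins, -1.06 at 2 to 40 Mb and -1.05 with 4 parts. The Xi's own eigenvector had an absolute correlation of 0.0213 with that of the Xa, so the -1.97 is not a difference in compartment strength.

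For dTAG minus DMSO on the Xa, the share beyond 10 Mb differed by -1.36 without the distal end, -1.31 with a minimum of 10 kb and -1.60 with 40 kb, and the share from 100 kb to 1 Mb by 2.08 and 2.31 with these minimums. The score at Xist differed by 0.056 with a flank of 10 Mb, -0.078 at 1 to 40 Mb and -0.070 at 10 to 60 Mb, and that at Dxz4 by -0.14 with a flank of 10 Mb. Boundary depth differed by -0.33 with a 200 kb diamond, -0.29 with raw counts, -0.32 when called on the other part of the pairs and -0.40 with a minimum depth of 0.4. Insulation SD differed by -0.059 with a 200 kb diamond and 0.018 with raw counts, and compartment strength by 0.037 on each file's own eigenvector and 0.11 at 2 to 40 Mb.

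For dTAG minus DMSO on the Xi, the share from 100 kb to 1 Mb differed by 1.3 without the distal end and the slope by -0.022 without smoothing. The score at Xist differed by -0.13 with a flank of 10 Mb, 0.00035 at 1 to 40 Mb and -0.023 at 10 to 60 Mb, and that at Dxz4 by -0.15 and -0.12 at the last 2 ranges. Boundary depth differed by -0.11 with a 200 kb diamond and -0.18 with a minimum depth of 0.4. Insulation SD differed by -0.035 with a mapping quality of at least 30 and 0.022 with raw counts, and compartment strength by 0.26 on each file's own eigenvector. The own eigenvectors of the Ctcf Xi files had absolute correlations of 0.0213 (DMSO) and 0.102 (dTAG) with that of Ctcf DMSO Xa and gave strengths of -0.43 and -0.16, so differences on them are not differences in compartment strength. The SD of the log2 coverage ratio was 0.046 and 0.036 in lanes 1 and 2 alone on the Xa, and 0.053 in lane 1 on the Xi.

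For Rad21 dTAG beside Ctcf DMSO, 96 of 199 values moved and 2 reversed. These 2 were compartment strength on the Xa, which differed by 0.014 and 0.10 in lanes 4 and 5 alone, and by -0.013 on each file's own eigenvector. On the Xi it differed by 0.32 and 0.31 in lanes 4 and 5. The score at Xist differed by -0.40 on the Xi with a flank of 10 Mb, and on the Xa by -0.23 with it, -0.28 at 1 to 40 Mb and -0.18 at 10 to 60 Mb. The ratio of Firre with Dxz4 on Rad21 dTAG Xi ranged over the 5 lanes from 0.291, in lane 1 alone, to 1.19, so lanes moved in both directions. Contacts of escape genes and silenced genes and a comparison with autosomes were not run. Depth limited the contact ratios between Firre, Dxz4 and Xist, which rested on 7 to 45 pairs in the Ctcf files.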

Other observations

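All values in this part were chosen after the data were seen. Few boundaries of the Xi were deep in the dTAG files. Of 50 boundaries with a depth of at least 0.2 on Ctcf DMSO Xi, 10 also reached it on Ctcf dTAG Xi and 6 on Rad21 dTAG Xi, and 5 boundaries reached it on both dTAG Xi files. At 53.6 Mb depth was 0.75 in Ctcf DMSO Xi, 0.64 in Ctcf dTAG Xi (0.53 to 0.76) and 0.26 in Rad21 dTAG Xi. The boundaries at 99.88 and 100.64 Mb, beside Xist, had 0.35 and 0.41 in Ctcf dTAG Xi, and that at 12.12 Mb had 0.34. The boundary at 157.52 Mb, with 0.54, lay beside the break in Xi contacts. The boundary at 150.48 Mb had 0.69 (0.53 to 0.85), but its bins held 343 ends in Ctcf DMSO Xa, the lowest of the 131 boundaries.

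Boundaries called anew in each file numbered 131 in Ctcf DMSO Xa, 116 in Ctcf dTAG Xa and 69 in Rad21 dTAG Xa, and 74, 32 and 39 on the Xi. Their mean depth was 0.60, 0.45 and 0.45 on the Xa, and 0.44, 0.53 and 0.38 on the Xi. In Ctcf DMSO Xa only the pairs left out of the first calling were used, in the other files all pairs. Simulated pairs without boundaries, fewer than those of the dTAG files, gave 38 calls.

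The first eigenvector took 17.7% of the eigenvalue sum in Ctcf DMSO Xa, 24.3% in Ctcf dTAG Xa and 48.6% in Rad21 dTAG Xa.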
